A study of Rattus norvegicus with 20 samples.

How the data were processed

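PolyA RNA libraries of hippocampus from 20 Gunn rat pups at postnatal day 6 were analysed, 5 per group in 4 groups defined by genotype (heterozygous Nj or homozygous jaundiced jj) and by phototherapy (none, or intermittent light from day 4, 12 h in total in cycles of 3 h). Per the labels each library came from a separate pup as far as can be read, and no replicate number links pups of different groups. The series description speaks of 6 untreated pups per group, and the 5 per group at hand were analysed here. The deposited table held raw read counts of the authors for 32883 rat Ensembl genes, with no normalisation. Per the submitters' processing notes, reads were checked with FastQC, aligned with TopHat2 2.0.13, counted with Subread and tested with edgeR. The notes name a mouse genome build while the identifiers are of rat genes; the rat build was not given in the sources used here, so no coordinates are given. No reads were realigned.

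Gene tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr by group, leaving 15272, normalised by TMM and fitted with all 20 libraries in 1 quasi-likelihood model with a mean per group (robust dispersion and robust fit, legacy estimates). The contrasts were tested on both sides with an F-test, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. CPM were computed from the TMM-scaled library sizes, and values are given as mean ± SD of 5 pups. DESeq2 1.42.0 (Wald test, same design) served as the second tool. It was run on all 32883 genes with its own filter, so its counts and those of edgeR come from different gene sets. Title prefixes follow the groups and could not enter as a covariate. No library was left out of the main fit.

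A set of 41 gene lists for cell types, brain regions, stress and signalling pathways, organelles and sex-linked genes was written before the data were examined; 39 had at least 3 measured members and were tested. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Calls by fry are those of its directional test unless its mixed test is named. With 5 against 5 libraries a chance share of 0.79 percent of genes would have CPM ranges that do not overlap. Genes were named by a rule fixed at the same time. Among genes past the threshold with an average log2 CPM of at least 1, ranges that do not overlap and a named symbol, the 10 largest rises and 10 largest falls were named. From each list called by camera or with 2 or more called members, up to 4 called members with the lowest p were added. A fixed set of genes of bilirubin handling, light and clock response, glia and neurons was always named, and where no gene passed, the 5 genes with the lowest p were named as not passing. Some genes that the rule names are not reported here; counts include them.

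Alternatives fixed beforehand were size factors of DESeq2, no count filter, a mean count of at least 10, the newer quasi-likelihood estimates, a Y-linked covariate, DESeq2, a fit of the compared groups alone, untreated Nj libraries of a single prefix, and leaving out each library in turn. Chosen after seeing the data were choroid plexus and meninges levels as covariates, leaving out libraries above 1000 CPM of Ttr, thinning to equal depth, and contrasts averaged over genotypes or treatments. Fold changes were also compared between contrasts across genes against 20 simulated data sets without change and, where contrasts share a group, with that group split 20 times. Group labels were regrouped in 100 splits per contrast.

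The pipeline was tested on simulated data in which known genes were changed within the fitted noise. At 1.25-fold it recovered 38.8, 34.3, 34.3, 40.3 and 7.5 percent of changed genes in the order jj against Nj untreated, light in Nj, light in jj, jj against Nj treated, and interaction. At 1.5-fold it recovered 62.7, 79.1, 65.7, 74.6 and 43.3 percent, and at 2-fold 92.4, 81.8, 89.4, 81.8 and 74.2 percent, with 6, 4, 9, 4 and 4 false calls. A list of 36 genes raised 1.15-fold was called by all 3 list tests, with 0 other lists called. Genes were drawn independently in these simulated data. In the real data the members of this list varied together (estimated correlation 0.147 for light in Nj). The self-test thus does not show how often false genes or lists are called in the real data. Most genes changed 1.25-fold were missed by the gene test in these simulated data, where a small share of genes was changed. Recovery after adjustment depends on that share, so it need not hold where many genes change. For light in Nj the called genes had a median absolute log2 change of 0.25, which is below 1.25-fold.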

Results

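Hippocampal RNA from 20 Gunn rat pups at postnatal day 6 was sequenced as polyA libraries. Gunn rats carry a loss-of-function mutation in Ugt1a1, the liver enzyme that conjugates bilirubin. Homozygous (jj) pups are jaundiced and heterozygous (Nj, written Jj in one label) pups are not. The pups fell into 4 groups of 5: untreated Nj, untreated jj, light-treated Nj and light-treated jj. Treated pups received intermittent LED phototherapy, the light used against neonatal jaundice, from day 4 for 12 h in total in cycles of 3 h. Total counts per library ran from 19.1 to 27.1 M (M for mega) in untreated Nj (mean 23.4 ± 3.3, SD) and from 16.9 to 22.1 M in untreated jj pups (19.1 ± 2.1). They ran from 19.5 to 23.1 M in treated Nj (21.2 ± 1.6) and 19.3 to 25.7 M in treated jj pups (21.2 ± 2.6). Of 32883 genes listed, 15272 passed the low-count filter and 10054 had 0 counts in every library. The lowest correlation between log2 counts per M (CPM) of libraries of a group, across genes, which are not independent replicates, was 0.972, in untreated jj.

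Hippocampus borders the choroid plexus, and Ttr, the transthyretin gene that choroid plexus expresses at very high levels, ran from 3.57 to 9660 CPM over the 20 libraries. Ttr passed 1000 CPM in 1 untreated Nj, 1 untreated jj, 2 treated Nj and 3 treated jj libraries. Transcripts of the Y chromosome (Kdm5d above 10 CPM) were present in 2, 2, 1 and 2 libraries of the groups in the same order. The sample titles carry a prefix that follows the groups: untreated Nj pups had 3 prefixes, untreated jj pups another, and both treated groups a further one. Its meaning is not stated. Among the contrasts below, treated jj against treated Nj is the one that lies within 1 prefix; elsewhere prefix and group cannot be told apart.

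**Figure D1:**
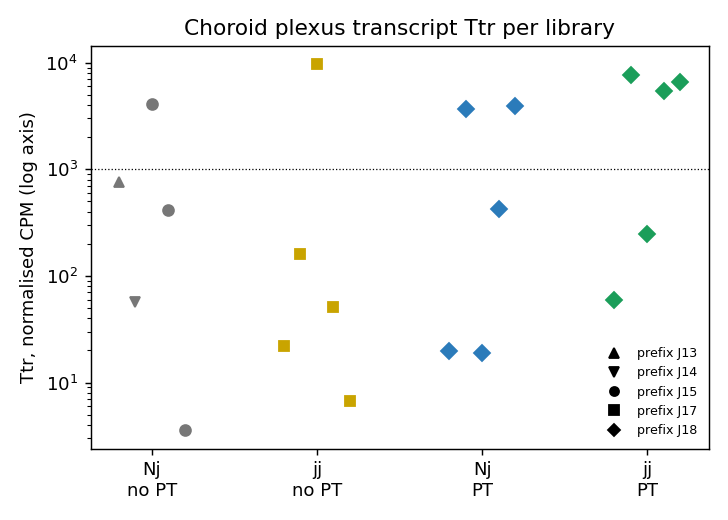
Ttr level of each library in CPM on a log axis, by group (5 libraries each). The 7 libraries above 1000 CPM come from all 4 groups, with 3 of them in the treated jj group.

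The comparison of untreated jj with untreated Nj pups addresses what jaundice does to hippocampal expression without light. Anp32a, an acidic nuclear protein that inhibits protein phosphatase 2A, had the lowest p: 24.9 ± 3.38 CPM (SD, n = 5) in jj and 40.6 ± 7.22 CPM in Nj pups, log2 fold change -0.70 (SE 0.12, edgeR adjusted p = 0.112). It did not pass. A second gene listed under the same symbol stood at 20.6 ± 0.96 and 23.4 ± 4.72 CPM, and the sum of both at 45.5 ± 3.87 and 64.0 ± 4.66 CPM. Whether reads were divided between them cannot be read from counts. Microglia genes and myelin genes lay on balance higher in jj pups, and genes of cholesterol synthesis and of immature neurons lower, by a median of at most 0.17 on the log2 scale and with no single member past the threshold. These calls were lost with an estimated correlation (adjusted p = 0.354, 0.504, 0.354 and 0.459 with an estimated correlation), fry called 0, and the myelin call was also lost without untreated Nj 4 or 5 or untreated jj 1 (highest 0.0892). The meninges list of neighbouring tissue had a larger median, 0.32 with 18 of 19 genes positive. The choroid plexus list had no settled direction: its median was 0.30 with 17 of 19 positive, but its mean log2 CPM was lower in jj (2.32) than in Nj pups (2.66). Camera did not call it (adjusted p = 0.925, 0.979 with an estimated correlation), yet placed it lower, at 4.78e-05, without the libraries above 1000 CPM of Ttr, of which untreated jj 3 is the only untreated jj library. Leaving these out was chosen after seeing the data. Genes of bilirubin and heme handling differed little. Blvrb, a biliverdin reductase, was at 21.8 ± 2.25 CPM in jj and 19.8 ± 1.29 in Nj pups (log2 0.14, adjusted p = 0.775). Hmox1, the inducible heme oxygenase, was at 7.79 ± 1.13 and 7.50 ± 0.85 CPM (log2 0.06, adjusted p = 0.913).

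Of 15272 genes, 0 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p under 0.05 there were 972 by edgeR, where 764 would be given by chance, and DESeq2 called 1, Anp32a (adjusted p = 0.000105). Without untreated Nj library 5, edgeR also called 1, Anp32a (log2 -0.79, SE 0.11, adjusted p = 0.0065). The next lowest p-values, none past the threshold, belonged to Pdzrn3, an E3 ubiquitin ligase (log2 0.20, adjusted p = 0.775), the unnamed LOC100361944 (log2 1.34), Adgre1, a macrophage receptor (log2 0.47), and Kcnq3, a potassium channel subunit (log2 0.19), each with the same adjusted p. The other genes fixed for display also did not pass: Dbp, a clock-controlled transcription factor (log2 0.27), Aif1, a microglial marker (0.31), Ugt1a5 (-0.42), Per1 (0.14) and Hmox2 (-0.08), all at adjusted p of 0.775 and more. Nor did Mbp (0.22), Gfap (0.13), Cirbp (0.06), Bdnf (-0.07), Calb1 (-0.08), Cyp1b1 (0.03), Blvra (0.02), Fkbp5 (0.02) and Rbm3 (-0.01). Ugt1a1 was not analysed here, and Cyp1a1 was below the filter.

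Over the fixed gene lists, camera with a preset correlation of 0.01 called 12 of 39, 7 higher and 5 lower in jj pups. Of these 0 were called with an estimated correlation (lowest adjusted p = 0.354 with an estimated correlation) and 0 by fry. Cholesterol synthesis had a median log2 change of -0.09 over 25 genes (camera adjusted p = 5.66e-06, 0.354 with an estimated correlation), microglia 0.17 over 22 (2.88e-05, 0.354) and ribosomal proteins 0.04 over 78 (0.00014, 0.504). The medians were, for glucocorticoid-responsive genes, 0.12 over 18 (0.00181, 0.425), immature neurons -0.09 over 21 (0.00227, 0.459) and heat shock -0.09 over 18 (0.00301, 0.354). In these 6 lists 0 genes passed, over all genes tested or adjusted over the list alone. A further 6 calls were each lost when 1 library was left out. Meninges fibroblasts (median 0.32, adjusted p = 0.000779, 0.743 with an estimated correlation) reached 0.128 without untreated Nj 2 or untreated jj 2, the higher value of both. Astrocytes (0.06, 0.00301, 0.549) reached 0.176 without untreated Nj 3 or untreated jj 2, and myelinating oligodendrocytes (0.16, 0.00692, 0.504) 0.0892 without untreated Nj 4 or 5 or untreated jj 1. Immediate early genes (-0.07, 0.0131, 0.44) reached 0.146 without untreated Nj 2 or 5 or untreated jj 1 or 5. Clock genes (0.07, 0.0285, 0.44), of which 3 rose when adjusted over the list alone, reached 0.17 without untreated Nj 3 or 5 or untreated jj 1 or 2. Proliferation genes (-0.05, 0.0491, 0.829) reached 0.476, losing the call without untreated Nj 2, 3, 4 or 5 or untreated jj 1, 2 or 3. Each of these values is the highest over the libraries named. Without the libraries above 1000 CPM of Ttr, an alternative chosen after seeing the data, the calls of heat shock (0.0671), astrocytes (0.334) and proliferation (0.602) were lost.

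The comparison of treated with untreated Nj pups addresses what phototherapy does in pups without jaundice. Some genes of immature neurons (4 of 21) and of dividing cells (8 of 35) fell, and some genes of calcium binding (4 of 16), of the respiratory chain (2 of 71), of the clock (3 of 17) and of microglia (3 of 22) rose. Camera called these 6 lists at the preset correlation and 0 of them with an estimated correlation (lowest adjusted p = 0.0527 with an estimated correlation). Gpc2, a glypican of developing axons (ENSRNOG00000001367), fell from 40.4 ± 8.01 to 24.1 ± 2.27 CPM (SD, n = 5; log2 -0.74, SE 0.11, edgeR adjusted p = 0.00126). Draxin, a repulsive axon guidance protein (ENSRNOG00000008911), fell from 53.9 ± 5.82 to 36.4 ± 2.20 CPM (log2 -0.57, SE 0.08, adjusted p = 0.00126). P2ry12, the purinergic receptor of resting microglia (ENSRNOG00000013902), rose from 7.54 ± 1.20 to 11.3 ± 0.59 CPM (log2 0.58, SE 0.10, adjusted p = 0.00267). Pvalb, the calcium-binding protein of fast-spiking interneurons, rose from 0.63 ± 0.17 to 1.23 ± 0.23 CPM (log2 0.96, SE 0.26, adjusted p = 0.0364). This low level is near the count filter, and the call held in 4 of 10 fits that left out a library. It was also lost with no count filter, after thinning and without the libraries above 1000 CPM of Ttr.

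In all, 611 of 15272 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 228 higher and 383 lower in treated pups, with a median absolute log2 change of 0.25. Of these 28 differed by more than 1.5-fold and 6 by more than 2-fold. DESeq2 called 1009, and 112 genes passed without the libraries above 1000 CPM of Ttr, an alternative chosen after seeing the data. Of these 112 genes, 84 were among the 611. Leaving out single libraries lowered the count from 611 to 152 without untreated Nj 4 and 159 without untreated Nj 5. Both libraries carry the prefix J15, as does untreated Nj 3, without which the count was 524. It was 593 without untreated Nj 1 (prefix J13) and 651 without untreated Nj 2 (J14). It was 253 without treated Nj 5 and 272 without treated Nj 2. With the J15 libraries as the only untreated Nj ones, 745 genes passed, 484 of them among the 611 (median fold ratio 1.138). All 611 genes kept their direction in each of these fits, as is likely where most libraries are those that picked the genes. Without the libraries above 1000 CPM of Ttr their median absolute log2 change was 0.23 (median SE 0.064) against 0.25 (median SE 0.059) in the fit of all libraries, a median fold ratio of 0.932.

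**Figure D2:**
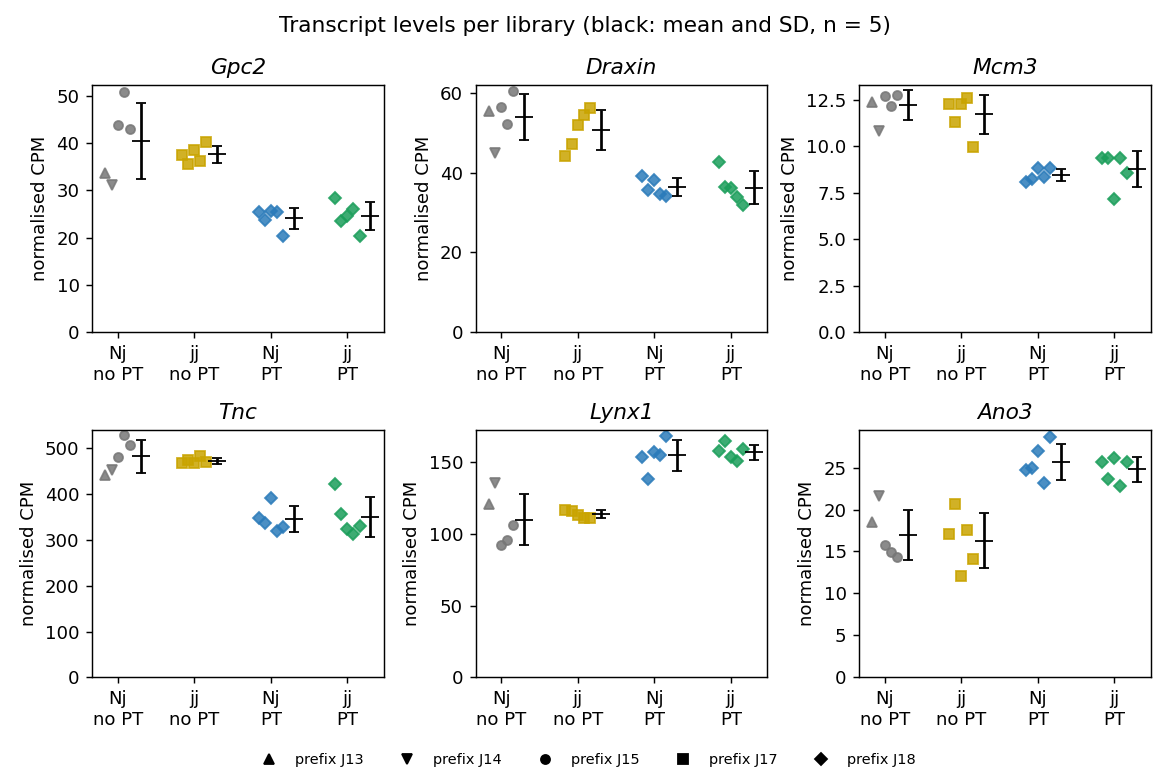
CPM of each library for named genes in the 4 groups, with the group mean and SD (n = 5 each). Gpc2 lay between 20.3 and 28.3 CPM in the 10 treated libraries and between 31.2 and 50.8 CPM in the 10 untreated ones.

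Among 21 measured genes of immature neurons, 4 fell and 17 did not pass, with 12 lower when adjusted over the list alone (median log2 -0.22; camera adjusted p = 9.61e-09, 0.0942 with an estimated correlation; fry 0.00205). Besides Draxin these were Sox11, a transcription factor of newborn neurons (log2 -0.48, SE 0.09, adjusted p = 0.00821). The others were the neuronal tubulins Tubb2b (2665 ± 153 to 2144 ± 200 CPM, log2 -0.31, adjusted p = 0.00649) and Tubb3 (1907 ± 130 to 1529 ± 150 CPM, log2 -0.32, adjusted p = 0.00875). Of 35 proliferation genes, 8 fell, 13 when adjusted over the list alone (median log2 -0.19; camera adjusted p = 1.01e-07, 0.23 with an estimated correlation; fry 0.012). They include parts of the replicative helicase, Mcm3 (12.2 ± 0.79 to 8.45 ± 0.34 CPM, log2 -0.52, adjusted p = 0.00216), Mcm2 (log2 -0.34, adjusted p = 0.0153) and Mcm6 (log2 -0.25, adjusted p = 0.0215). Rrm2, a subunit of ribonucleotide reductase, also fell (log2 -0.50, adjusted p = 0.0305).

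Of 16 calcium-binding genes, 4 rose, 6 when adjusted over the list alone, and every one of the 16 had a positive fold change (median log2 0.16; camera adjusted p = 1.18e-07, 0.0527 with an estimated correlation; fry 0.000867). Besides Pvalb these were Vsnl1, a neuronal calcium sensor (182 ± 17.8 to 254 ± 8.13 CPM, log2 0.48, adjusted p = 0.0174), Ncald (log2 0.21, adjusted p = 0.0336) and S100b, which astrocytes express (log2 0.27, adjusted p = 0.0325). Calb1, calbindin, did not pass (52.2 ± 5.44 and 66.9 ± 17.8 CPM, log2 0.36, adjusted p = 0.19). Of 71 nuclear genes of the respiratory chain, 2 rose, Cox7c (log2 0.18, adjusted p = 0.0381) and Sdhd (log2 0.15, adjusted p = 0.0403). There were 9 when adjusted over the list alone (median log2 0.09; camera adjusted p = 2.24e-08, 0.23 with an estimated correlation; fry 0.0156). The 13 genes of the mitochondrial genome had a median log2 change of 0.16 with 0 members past the threshold (camera adjusted p = 0.022, 0.863 with an estimated correlation), a call lost without untreated Nj 4 (0.115).

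Of 22 microglia genes, 3 rose, 4 when adjusted over the list alone (median log2 0.15; camera adjusted p = 0.000333, 0.305 with an estimated correlation; fry 0.0306). They were P2ry12, Ctss, a lysosomal protease (log2 0.37, adjusted p = 0.028), and Aif1 (8.66 ± 1.21 to 11.4 ± 1.41 CPM, log2 0.39, adjusted p = 0.0486). Of 17 clock genes, 3 rose, 7 when adjusted over the list alone (median log2 0.12; camera adjusted p = 0.00556, 0.227 with an estimated correlation; fry 0.012). These included Nr1d2, a nuclear receptor that represses clock genes (log2 0.33, adjusted p = 0.0231). The others were the PAR bZIP factors Dbp (19.7 ± 2.43 to 24.6 ± 0.61 CPM, log2 0.32, adjusted p = 0.0323) and Tef (log2 0.16, adjusted p = 0.0398). Of 36 genes of glutamatergic synapses, Grin2c, an NMDA receptor subunit (log2 0.79, SE 0.16, adjusted p = 0.0119), and Nrgn, a calmodulin-binding postsynaptic protein (log2 0.27, adjusted p = 0.0186), rose. Of the list 8 were higher and 1 lower when adjusted over the list alone (median log2 0.08; camera adjusted p = 0.000451, 0.392 with an estimated correlation; fry 0.0523). Of 12 dentate gyrus genes, 0 passed, 3 when adjusted over the list alone (median log2 0.16; camera adjusted p = 0.022, 0.116 with an estimated correlation; fry 0.000867).

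Of 25 genes of cholesterol synthesis, 4 fell, over all genes and adjusted over the list alone. Among them were Srebf2, the transcription factor that drives the pathway (log2 -0.21, adjusted p = 0.0172), and Dhcr7, an enzyme of the pathway (log2 -0.21, adjusted p = 0.0296). The list median was -0.04 (camera adjusted p = 0.0463, 0.728 with an estimated correlation), and the list call was lost without untreated Nj 1 or 2 or treated Nj 4 or 5 (highest adjusted p = 0.231). Red blood cell genes (10 measured, 0 past the threshold, median log2 -0.34; camera adjusted p = 0.022, 0.637 with an estimated correlation) lost their call without untreated Nj 3 or treated Nj 2 (highest 0.121). Myelinating oligodendrocyte genes (18 measured, 0 past the threshold, median 0.19; camera adjusted p = 0.0238, 0.637 with an estimated correlation) lost theirs without untreated Nj 1, 4 or 5 or treated Nj 1, 3 or 5 (highest 0.0944). Camera called 12 of 39 lists, 0 with an estimated correlation, and fry called 7. The calls of dentate gyrus (0.0617), red blood cells (0.08), myelinating oligodendrocytes (0.08) and cholesterol synthesis (0.0965) were lost without the libraries above 1000 CPM of Ttr. Lists of neighbouring tissue were not called but had medians as large: choroid plexus 0.32 with 18 of 19 genes positive (camera adjusted p = 0.68, 0.955 with an estimated correlation), meninges -0.22 with 16 of 19 negative (0.308, 0.924) and ependyma -0.22 with 11 of 11 negative (0.0523, 0.738). Without the Ttr-rich libraries choroid plexus turned lower and was called (0.0366), and ependyma was called lower (1.88e-06).

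Several lists that camera did not call held changed members in both directions. Among interneuron genes 2 rose and 4 fell. Pvalb and Sst, somatostatin (log2 0.29, adjusted p = 0.0192), rose. Reln, the extracellular guidance protein reelin (658 ± 74.1 to 501 ± 25.7 CPM, log2 -0.39, adjusted p = 0.00278), and Dlx2, a transcription factor of developing interneurons (log2 -0.43, adjusted p = 0.0398), were among those that fell. Of astrocyte genes, Slc1a2, the main glial glutamate transporter (log2 0.36, adjusted p = 0.00596), Ntsr2 (log2 0.78, adjusted p = 0.00925) and S100b rose, and Aldh1l1 fell (log2 -0.31, adjusted p = 0.0469). In glycolysis Pfkp (165 ± 19.4 to 221 ± 13.3 CPM, log2 0.42, adjusted p = 0.00216) and Pgam1 (log2 0.18, adjusted p = 0.0219) rose, and Pfkl (log2 -0.25, adjusted p = 0.0404) and Hk1 (log2 -0.15, adjusted p = 0.0261) fell. In the stress list Ddit3, encoding CHOP, rose (log2 0.47, adjusted p = 0.0192). Phgdh, the first enzyme of serine synthesis (log2 -0.32, adjusted p = 0.00859), and Ddit4 (log2 -0.22, adjusted p = 0.0396) fell. Both interferon-list genes that passed rose, B2m (log2 0.24, adjusted p = 0.00925) and Ifit2 (log2 0.38, adjusted p = 0.0423).

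Among genes with the largest changes outside these lists, Il34, a ligand of the microglial receptor Csf1r (log2 0.50, adjusted p = 0.00706), Ano3 (0.59, 0.00925), Sptssb, a subunit of serine palmitoyltransferase (0.56, 0.00963), and Rgs6 (0.60, 0.0337) rose. So did Nppa, natriuretic peptide A (0.59, 0.0342), Slc15a1 (0.58, 0.0486), Ap1s3 (0.56, 0.0398), Rwdd3 (0.52, 0.0326) and Ipcef1 (0.51, 0.0354). Zbtb12 (log2 -0.61, adjusted p = 0.000774), Parp16 (-0.68, 0.0443), Emilin3 (-0.68, 0.0176) and Dmrta2, a factor of cortical progenitors (-0.66, 0.0291), fell. So did Avpr1a, a vasopressin receptor (-0.59, 0.0338), Vwa2 (-0.54, 0.0327) and Efna4 (-0.53, 0.0306). Of the genes fixed for display, Dbp and Aif1 passed. The rest did not: Blvra (log2 0.15, adjusted p = 0.18), Bdnf (0.19, 0.27), Mbp (0.28, 0.34), Gfap (0.18, 0.389), Hmox1 (-0.18, 0.425), Ugt1a5 (0.32, 0.427), Cirbp (-0.09, 0.343). Further ones were Hmox2 (0.06, 0.55), Cyp1b1 (0.11, 0.583), Fkbp5 (-0.08, 0.586), Blvrb (0.06, 0.734), Rbm3 (0.05, 0.778) and Per1 (0.00, 0.996). Of the 59 named genes that passed, 18 also passed with each library left out in turn: Zbtb12, Draxin, Gpc2, Mcm3, Pfkp, P2ry12, Reln, Slc1a2, Tubb2b, Il34, Sox11, Phgdh, Tubb3, Ano3, B2m, Ntsr2, Sptssb and Grin2c. Without the libraries above 1000 CPM of Ttr, an alternative chosen after seeing the data, 11 of these 18 lost their call: Gpc2, Pfkp, Reln, Slc1a2, Tubb2b, Sox11, Ano3, B2m, Ntsr2, Sptssb and Grin2c. In that fit the folds of the 611 genes stayed about as large (median ratio 0.932). The other 41 named genes lost their call without at least 1 library, most often untreated Nj 4 or 5 or treated Nj 2 or 5, which lowered the whole count as above.

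The comparison of treated with untreated jj pups addresses what phototherapy does under jaundice. Tnc, the extracellular matrix protein tenascin-C (ENSRNOG00000058645), fell from 472 ± 6.61 to 349 ± 43.8 CPM (SD, n = 5; log2 -0.44, SE 0.07, edgeR adjusted p = 0.0141). Gpc2 fell from 37.6 ± 1.85 to 24.6 ± 2.92 CPM (log2 -0.61, SE 0.11, adjusted p = 0.0242). Lynx1, a membrane modulator of nicotinic receptors (ENSRNOG00000006086), rose from 114 ± 2.56 to 157 ± 5.27 CPM (log2 0.47, SE 0.08, adjusted p = 0.0141). On balance the lists of immature neurons and proliferation lay lower, and those of the respiratory chain, calcium binding and the clock higher, in treated pups, with 1 of 21, 1 of 35, 0 of 71, 0 of 16 and 0 of 17 members past the threshold. These camera calls were all lost with an estimated correlation (adjusted p from 0.186 to 0.398 with an estimated correlation), and fry did not call proliferation (0.0976). The choroid plexus list lay 1.01 log2 units higher and the meninges list -0.40 in treated jj pups, where 3 of 5 libraries passed 1000 CPM of Ttr against 1 of 5 untreated.

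Of 15272 genes, 25 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 higher and 19 lower, with 1978 at an unadjusted p under 0.05. DESeq2 called 271. Lower were also Adamts7, a metalloprotease of the matrix (log2 -0.53, adjusted p = 0.0141), Draxin (50.7 ± 4.99 to 36.2 ± 4.09 CPM, log2 -0.48, adjusted p = 0.0199) and Fat4, a giant cadherin (log2 -0.43, adjusted p = 0.0228). The same held for Fbn2, fibrillin 2 (log2 -0.52, adjusted p = 0.0342), Mcm3 (log2 -0.41, adjusted p = 0.0459) and Zfp663 (log2 -0.52, adjusted p = 0.0459). Others were Gli2, a transcription factor of hedgehog signalling (log2 -0.41, adjusted p = 0.0473), and the unnamed clone AC141959.1 (log2 -0.47, adjusted p = 0.0418). Tuba4a, an alpha tubulin (log2 0.33, adjusted p = 0.0199), Ano3 (log2 0.61, adjusted p = 0.0418), Mical2, which oxidises actin (log2 0.26, adjusted p = 0.0418), Ttll7, a tubulin polyglutamylase (log2 0.23, adjusted p = 0.0493), and Adarb1, an RNA-editing deaminase (log2 0.20, adjusted p = 0.0493), rose. Of the genes fixed for display 0 passed: Hmox2 (log2 0.15, adjusted p = 0.18), Dbp (0.19, 0.326), Calb1 (0.29, 0.419), Per1 (-0.15, 0.42), Cirbp (-0.09, 0.462), Gfap (0.18, 0.479), Blvrb (-0.11, 0.498), and Fkbp5 (-0.12, 0.508). Further ones were Hmox1 (-0.17, 0.521), Mbp (0.23, 0.542), Bdnf (0.13, 0.566), Ugt1a5 (0.29, 0.573), Cyp1b1 (-0.13, 0.584), Aif1 (0.10, 0.742), Blvra (0.04, 0.819) and Rbm3 (0.03, 0.911).

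The 25 calls rested on the libraries and the fit used. The count was 0 without untreated jj 4 or treated jj 2, 3 or 5, 5 without treated jj 4 (Lynx1, Cachd1, Adamts7, Fbn2 and Tnc, named after their values were seen), 16 without untreated jj 1, 39 without untreated jj 3 and 43 without treated jj 1. It was 3 with the groups of the contrast alone in the fit (Gpc2, Lynx1 and Adamts7) and 13 with a Y-linked covariate. It was 14 after thinning to equal depth, and 0 with choroid plexus and meninges covariates or without the libraries above 1000 CPM of Ttr, these 3 chosen after seeing the data. In each of these fits all 25 genes kept their direction, as is likely where most libraries are those that picked the genes. Their median absolute log2 change of 0.41 (median SE 0.069) became 0.34 (median SE 0.083) with the covariates and 0.35 (median SE 0.103) without those libraries, at median fold ratios of 0.925 and 0.923. The calls were thus lost with somewhat smaller folds and larger errors. No named gene passed in more than 6 of the 10 fits that left out 1 library.

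Camera called 12 of 39 lists, 0 with an estimated correlation (lowest adjusted p = 0.186 with an estimated correlation), and fry called 5. Respiratory chain genes had a median log2 change of 0.10, with 67 of 71 positive and 0 past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 1.18e-12, 0.188 with an estimated correlation; fry 0.02). Immature neuron genes had a median of -0.17, with 1 gene, Draxin, past the threshold and 6 lower when adjusted over the list alone (1.21e-06, 0.188; fry 0.0273). Calcium-binding genes had a median of 0.13, with 0 past the threshold and 2 higher when adjusted over the list alone (6.8e-06, 0.186; fry 0.02). Proliferation genes had -0.12, with 1, Mcm3, past the threshold and 4 lower when adjusted over the list alone (2.47e-05, 0.398; fry 0.0976). Meninges genes had a median of -0.40, with 0 past the threshold and 8 lower when adjusted over the list alone (2.09e-07, 0.5). Ribosomal protein genes had -0.07, with 0 past the threshold and 1 lower when adjusted over the list alone (1.21e-06, 0.394). The remaining calls were each lost without 1 library. Clock genes (0.10, 2 higher when adjusted over the list alone; camera 0.00985, 0.336 with an estimated correlation; fry 0.0448) reached 0.0847 without untreated jj 5. Glutamatergic genes (0.06, 1 higher and 1 lower when adjusted over the list alone; 0.00775, 0.604) reached 0.108 without untreated jj 1. Mitochondrially encoded genes (0.15; 0.00393, 0.689) reached 0.708 without untreated jj 3. The choroid plexus list (camera 0.00433, 0.707 with an estimated correlation) was lost without untreated jj 5 or treated jj 2, 4 or 5 (highest 0.115). Cholesterol synthesis (0.08; 0.033, 0.689) was lost without untreated jj 1, 3 or 4 or treated jj 1 (highest 0.103). Hypoxia and glycolysis genes (0.02, 4 higher when adjusted over the list alone; 0.0435, 0.394) were lost without untreated jj 1, 2, 4 or 5 or treated jj 1, 2 or 4 (highest 0.0995). Dentate gyrus genes were called by fry alone (median 0.09, fry 0.0273; camera 0.0968). Clock genes (0.189), hypoxia and glycolysis (0.226), choroid plexus (0.651), cholesterol synthesis (0.0939) and mitochondrially encoded genes (0.0756) also lost their calls without the libraries above 1000 CPM of Ttr.

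**Figure D3:**
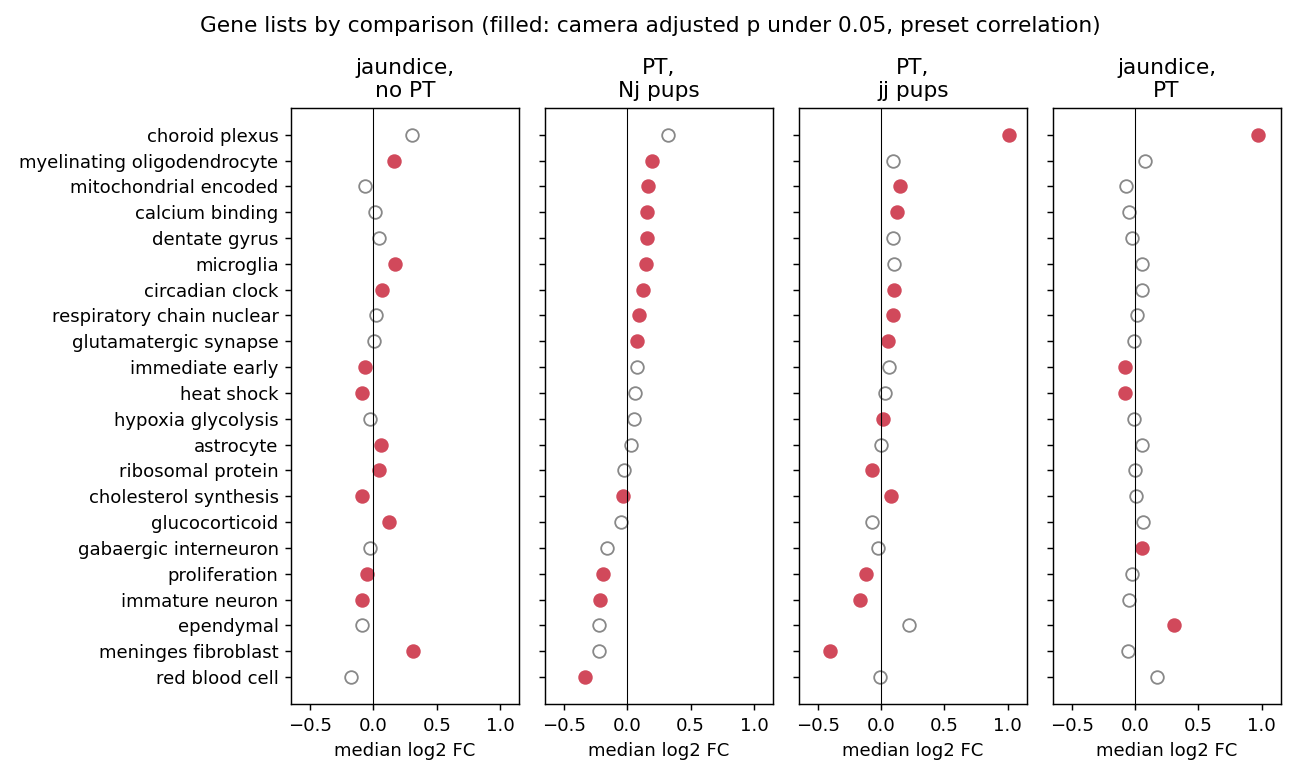
Median log2 fold change of fixed gene lists in each contrast, with the lists called by camera at the preset correlation marked. Immature neuron genes stood at -0.22 in Nj and -0.17 in jj pups for phototherapy, and the choroid plexus list at 1.01 in jj pups.

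Light-treated jj and Nj pups, compared with each other, address what jaundice leaves after phototherapy, within a single title prefix. The lowest p belonged to Tra2a, a splicing regulator (47.2 ± 3.69 CPM in jj and 56.4 ± 2.20 CPM in Nj pups, SD, n = 5; log2 -0.26, SE 0.05, edgeR adjusted p = 0.371), which did not pass. Sltm (log2 -0.22), Acss1, a mitochondrial acetyl-CoA synthetase (0.30), Arrdc3 (-0.52) and Chsy3, a chondroitin synthase (-0.55), each at adjusted p = 0.713, came next. The choroid plexus list lay 0.97 log2 units higher in treated jj pups, with 3 of 5 against 2 of 5 libraries above 1000 CPM of Ttr.

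By edgeR's quasi-likelihood test 0 of 15272 genes passed, with 1011 at an unadjusted p under 0.05 against 764 given by chance. DESeq2 called 2, Tra2a (log2 -0.26, adjusted p = 0.0109) and LOC103689971 (log2 3.15, adjusted p = 0.0109). The latter, named after its values were seen, was the 1 gene called without treated jj 1 (log2 3.44, SE 0.40, edgeR adjusted p = 0.000298). The genes fixed for display did not pass: Cyp1b1 (log2 -0.21, adjusted p = 0.724), Ugt1a5 (-0.44, 0.724), Dbp (0.14, 0.724), Blvra (-0.09, 0.724), Bdnf (-0.13, 0.724), and Gfap (0.14, 0.743). Nor did Cirbp (0.06, 0.758), Mbp (0.17, 0.76), Calb1 (-0.15, 0.779), Hmox1 (0.06, 0.891), Rbm3 (-0.03, 0.923), Blvrb (-0.03, 0.924), Aif1 (0.02, 0.971), Fkbp5 (-0.01, 0.972), Per1 (-0.01, 0.979) and Hmox2 (0.00, 0.983). Camera called 5 lists, and 0 with an estimated correlation or by fry. Ependymal genes had a median log2 change of 0.31 (camera adjusted p = 0.000101, 0.713 with an estimated correlation), interneuron genes 0.06 with 2 higher when adjusted over the list alone (0.00752, 0.779) and heat shock genes -0.08 (0.00752, 0.713). Immediate early genes (-0.07; 0.0189, 0.713 with an estimated correlation) lost the call without treated Nj 3 or treated jj 2 or 3 (highest 0.137), and choroid plexus (0.0189, 0.846) without treated Nj 1, 3 or 4 or treated jj 2, 4 or 5 (highest 0.331). Immediate early genes (0.103), heat shock (0.52), choroid plexus (0.895) and interneurons (0.0559) lost their calls without the libraries above 1000 CPM of Ttr. The count of lists for that fit, given below, includes a call gained there.

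Whether phototherapy acted differently in jj and Nj pups was tested as an interaction. Among the lowest p-values were those of Tsnaxip1 (log2 difference 1.27, SE 0.29, n = 5 per group), Myh6 (1.31, SE 0.31), Coa6 (-0.79, SE 0.19) and Anp32a (0.70, SE 0.17), each at an edgeR adjusted p of 1. Anp32a stood at 40.6 ± 7.22 and 28.4 ± 4.12 CPM in untreated and treated Nj pups and at 24.9 ± 3.38 and 28.3 ± 2.31 CPM in jj pups. The second gene under this symbol went the other way in Nj pups, at 23.4 ± 4.72 and 32.6 ± 11.3 CPM. It stood at 20.6 ± 0.96 and 23.3 ± 3.2 CPM in jj pups. The sum of both was 64 ± 4.66 and 61 ± 11.4 CPM in Nj and 45.5 ± 3.87 and 51.6 ± 2.56 CPM in jj pups. By edgeR's quasi-likelihood test 0 genes passed, with 521 at an unadjusted p under 0.05 against 764 given by chance. DESeq2 called 0. Without treated jj 1, LOC103689971 passed (log2 4.71, SE 0.69, adjusted p = 0.0133). Camera called 9 lists and 0 with an estimated correlation (lowest adjusted p = 0.565 with an estimated correlation) or by fry. The larger count in Nj than in jj pups is therefore not shown to be a difference in response. The genes fixed for display had adjusted p of 1 and differences from -0.29 for Aif1 to 0.09 for Hmox2.

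The difference between light-treated and untreated pups ran in the same direction in both genotypes for most called genes. Both treated groups carry the same title prefix, which no untreated pup carries. A difference that goes with the prefix would therefore also give this agreement. Of the 611 genes called in Nj pups, 589 (96.4 percent) had the same sign in jj pups and 378 an unadjusted p under 0.05 there, with a median ratio of the log2 fold changes (jj over Nj) of 0.59. Genes picked by their change in Nj pups tend to show a smaller one elsewhere, so this ratio does not show a weaker response in jj pups. Of the 25 called in jj pups, 25 had the same sign in Nj pups and 20 an unadjusted p under 0.05. Their median ratio (Nj over jj) was 0.978. Called in both were 6 higher genes, where 0.09 would be expected of independent lists, and 12 lower, where 0.48 would be expected. The call lists are not fully independent, as 1 fit of all 20 libraries set the spread for both, and with the compared groups alone in the fit 3 genes were called in jj pups. By edgeR 0 genes were called in opposite directions. Over all 15272 genes, which are not independent replicates, 69.9 percent had the same sign and the fold changes correlated at r = 0.29 (rho 0.46) across genes, against 0.018 ± 0.072 in simulated data without change. The r was 0.067 without treated Nj 5, and its jackknife SE over libraries was 0.258. The simulation drew each gene independently, so its spread leaves out variation that genes share between libraries. Averaged over genotypes, a contrast chosen after seeing the data, phototherapy was called for 1541 genes, 664 higher and 877 lower. Jaundice averaged over treatments was called for 0 by edgeR, with 1709 at an unadjusted p under 0.05, and DESeq2 was not run on these averages.

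**Figure D4:**
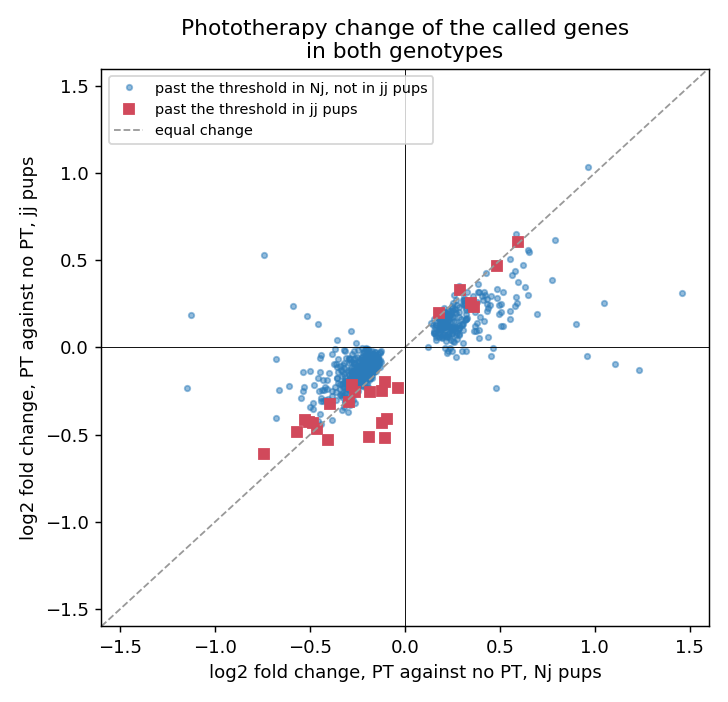
Log2 fold change of phototherapy in jj pups against that in Nj pups, 1 point per gene, with the genes past the threshold marked. Of the 611 genes called in Nj pups, 589 lie in the quadrants of equal sign.

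The jaundice effect without light and the jaundice effect under light correlated at r = 0.15 (rho 0.29) across genes, with 0.007 ± 0.058 in simulated data. This r was -0.29 without untreated jj 3 (jackknife SE 0.425). The simulated spreads given here also come from genes drawn independently. The jaundice effect without light and the phototherapy effect in jj pups share the untreated jj libraries and correlated at r = -0.35 (rho -0.30) across genes. This r ran from -0.686 without untreated jj 3 to -0.178 without untreated Nj 3 (jackknife SE 0.407). Simulated groups without change gave -0.49 ± 0.058 through the shared libraries alone. With the shared group split between both effects r averaged 0.082 over 20 splits, from -0.096 to 0.297, so the negative correlation was not seen on average once no library was shared.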

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

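The fits without libraries rich in Ttr were chosen only after the result was seen, the other tests of this part before. Of 396 group values, those of 98 named genes and of total counts, 19 held a library set apart from the other 4 by Dixon's ratio, where 19.8 would be given by chance, and no library held more than 3 of them. Among them, gap over range was 0.754 for Anp32a and 0.729 for Srebf2 in untreated jj 3, 0.746 for Gfap, 0.722 for Il34 and 0.749 for Arrdc3 in untreated jj 5, 0.841 for Ctss in untreated jj 2 and 0.821 for Parp16 in untreated jj 1. In untreated Nj pups it was 0.723 for LOC100361944 in library 5, 0.822 for Slc1a2 and 0.796 for Grin2c in library 2, and 0.733 for Pvalb in library 3. In treated Nj pups it was 0.928 for Aif1 and 0.751 for Coa6 in library 3 and 0.74 for Calb1 in library 4. In treated jj pups it was 0.734 for Aif1 and 0.802 for Blvrb in library 2, and 0.802 for Ttll7 in library 3. The count was no larger than chance would give, and all libraries stayed in.

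Camera with the preset correlation called 9 gene lists for a phototherapy effect that differed between jj and Nj pups, 0 with an estimated correlation and 0 by fry. Cholesterol synthesis (median difference 0.11, adjusted p = 7.05e-07, 0.565 with an estimated correlation), ependymal genes (0.41, 5.57e-06, 0.699) and meninges (-0.33, 0.00021, 0.899) were called with each library left out. The others were not. Red blood cells (0.34, adjusted p = 0.00872, 0.899 with an estimated correlation; lost without untreated Nj 3, untreated jj 5 or treated jj 4, highest 0.101) lost the call, as did interneurons (0.07, 0.00962, 0.899; lost without untreated Nj 4, untreated jj 1, treated Nj 5 or treated jj 4, highest 0.129). The same held for ribosomal proteins (-0.03, 0.00962, 0.899; lost without untreated Nj 1, untreated jj 3 or 5, treated Nj 1 or treated jj 3 or 5, highest 0.241) and microglia (-0.13, 0.0109, 0.899; lost without untreated jj 1 or 3, treated Nj 4 or 5 or treated jj 1 or 3, highest 0.115). Choroid plexus (0.64, adjusted p = 0.0324, 0.899 with an estimated correlation) was lost without untreated Nj 1 or 3, untreated jj 1, 2, 4 or 5, treated Nj 1, 3 or 4 or treated jj 2, 4 or 5 (highest 0.722). Endothelial cells and pericytes (-0.06, 0.0476, 0.899) were lost without untreated Nj 2, 4 or 5, untreated jj 1, 3 or 4, treated Nj 2, 4 or 5 or treated jj 1, 2 or 3 (highest 0.419). Without the libraries above 1000 CPM of Ttr red blood cells (0.562) and endothelial cells and pericytes (0.174) also lost the call.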

How the results depend on the processing

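Covariates for choroid plexus and meninges, leaving out libraries above 1000 CPM of Ttr, thinning and averaged contrasts were chosen only after the result was seen. No paired analysis was possible because the labels carry no replicate number shared between groups. For jaundice without light the count of 0 genes became 1 with DESeq2 and 0 to 1 when libraries were left out (1 without untreated Nj 5). For phototherapy in Nj pups 611 genes became 1009 with DESeq2, 112 without the libraries above 1000 CPM of Ttr, and 152 (without untreated Nj 4) to 651 (without untreated Nj 2) on leaving out libraries. For phototherapy in jj pups 25 genes became 271 with DESeq2, 13 with the Y-linked covariate, 3 with the compared groups alone, 14 after thinning, 0 with the choroid plexus and meninges covariates, 0 without the libraries above 1000 CPM of Ttr, and 0 (without untreated jj 4) to 43 (without treated jj 1). For jaundice among treated pups 0 genes became 2 with DESeq2 and 0 to 1 (without treated jj 1), and for the interaction 0 became 0 to 1 (without treated jj 1). Phototherapy averaged over genotypes, 1541 genes, gave 603 with the covariates and 424 without the libraries above 1000 CPM of Ttr. Fewer libraries remain in several of these fits, which by itself lowers counts; beyond that, the cause was not tested.

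With an estimated correlation 0 gene lists were called in each of the 5 contrasts. Fry called 0 for jaundice without light, 7 for phototherapy in Nj, 5 for phototherapy in jj, 0 for jaundice among treated pups and 0 for the interaction. Its mixed test, which counts changes in either direction, called 2, 21, 14, 0 and 0 in the same order. For jaundice without light these were clock genes (mixed adjusted p = 0.0154) and microglia (0.032). Without the libraries above 1000 CPM of Ttr, 12 lists became 7 for phototherapy in jj pups and 5 became 2 for jaundice among treated pups. Leaving out libraries gave 3 (without treated Nj 3) to 7 (without treated Nj 1) for jaundice among treated pups and 5 (without untreated jj 1) to 12 (without untreated Nj 2) for the interaction. The correlation of both jaundice effects, 0.151, turned to -0.084 without the libraries above 1000 CPM of Ttr. The cause was not tested. Depth, 16.9 to 27.1 M counts, limits what can be said of genes below the count filter, among them Cyp1a1.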

Other observations

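The tests by regrouping libraries, both tests of the choroid plexus pattern, and the fits with covariates or thinned counts were chosen only after the result was seen. Many transcripts were higher or lower in light-treated Nj pups. Random regrouping of the 10 Nj libraries argues against luck of the draw among single pups: 1 of 100 splits, the real one, gave as many genes, and the highest other gave 32. The real split also parts the title prefixes, so regrouping single pups cannot decide on luck of the draw between prefixes. With choroid plexus and meninges levels as covariates the median fold ratio was 0.971. This argues against choroid plexus and meninges carried into some dissections as the source of most of these folds. Other neighbouring tissue, such as ependyma, was not a covariate, so the ratio cannot decide on it. Thinning to equal depth gave a ratio of 0.996. Thinning leaves the expected folds as they are, so this ratio cannot decide on sequencing depth. Of the 611 genes, 478 were called again at equal depth, so most calls did not need unequal counts. Title prefix cannot be told apart from light, as no prefix holds pups with and without light. On a score of 200 genes from the jj phototherapy contrast, untreated Nj prefixes lay 0.162 apart at the widest (J14 -0.018, J15 -0.181). This was 0.655 times the gap of 0.248 between treated and untreated Nj pups, and J13 (-0.088) and J14 are single libraries. All treated Nj libraries (lowest 0.075) lay above all untreated ones (highest -0.018), which light or prefix would each give. Further hippocampal maturation also cannot be told apart: Grin2a over Grin2b was higher in treated pups of both genotypes pooled (exact permutation p = 0.0119), by 0.219 in Nj pups (exact permutation p = 0.151) and 0.242 in jj pups (exact permutation p = 0.0397), whereas Slc12a5 over Slc12a2 differed by 0.059 in Nj and -0.109 in jj pups (pooled exact permutation p = 0.83), and Slc12a2 is also expressed by choroid plexus.

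For phototherapy in jj pups 7 of 100 splits, the real one among them, gave at least as many genes, up to 413, and the 5 splits with the most genes put all 4 jj libraries above 1000 CPM of Ttr on one side, which points to a structure of the samples. The count of 25 genes is thus not beyond what regrouping the jj libraries gives. The fold changes in Nj pups, taken from other libraries, had the same sign for 25 of the 25 genes, and 6 of the 6 higher and 12 of the 19 lower ones were called there too. Both call lists share the spread estimated from all 20 libraries, and 3 genes were called with the compared groups alone, so these overlaps are not those of independent lists. The treated pups of both genotypes also share a title prefix, so a prefix difference would give the same overlaps. For jaundice without light, jaundice among treated pups and the interaction the real count was 0, so 100, 100 and 100 splits gave as many by construction and the regrouping says nothing.

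Choroid plexus transcripts varied from library to library. The members of the list followed Ttr with a median r of 0.947. The list mean without Ttr correlated with Ttr at Pearson r = 0.968 and Spearman rho = 0.983 over 20 libraries (permutation p = 1e-05 each). The r was 0.98 without the 2 farthest libraries, 0.974 within the 7 libraries above 1000 CPM and 0.94 within the other 13. This is in line with choroid plexus tissue present in some dissected lobes. The spread of group means had a permutation p of 0.568, so genotype or phototherapy group as a further source cannot be told apart from none.

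A few genes switched between near 0 and a high level. Of 6 found, 2 were Y-linked, and of the 4 left 2 had an opposite partner and 3 were tied to Kdm5d. Ddx3 was high where Kdm5d was, and AABR07039356.2 and Gm27733 were high in the 13 libraries without Kdm5d and near 0 in the 7 with it. The state of these 3 thus went with the sex of the pups in all 20 libraries. The partner search cannot decide on reads shared between near-identical gene copies, and 4 genes are too few. The partner of AABR07039356.2 was Y-linked Eif2s3y (r -0.942), and that of Ddx3 was AABR07039356.2 (r -0.939). Sex by itself gives both opposite patterns. Gm27733 had no partner. The gene that did not go with sex was Selenow. It had a mean of 129 CPM in the 2 libraries above the middle of its range and 4.92 CPM in the others. The search for switching genes used another cut, by which more libraries count as high for Selenow.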
